A study of Saccharomyces cerevisiae with 14 samples.

How the data were processed

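Gene expression was measured with 1-colour Agilent arrays in 14 yeast cultures, 7 of a wild-type strain and 7 of a strain with RNH201 replaced by a hygromycin resistance cassette. Per the labels' protocols, individual colonies were grown overnight in rich medium to mid-log phase, total RNA was isolated with a commercial yeast kit and Cy3-labelled cRNA was made from it. The labels give the cell density of the cultures as a range, not per culture. The series design calls the samples biological replicates, 3 per strain from one batch and 4 from another, strain was taken from the sample labels, and batch from the form of the sample titles and those numbers. The labels call every culture untreated and mid-log. Each pair of replicate arrays of a group differed by more than spot error, with a mean squared difference at least 4.12 times as large.

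The deposited scanner files hold spot intensities on a linear scale, 43792 gene spots and 1417 control spots per array. Per the file headers, images were read with Agilent Feature Extraction 9.5.3.1 (9.5 in the submitters' processing notes), which flagged outlier spots, subtracted a spatially detrended background, detrended the signal across the array and put surrogate values in place of low signals. The processed intensity that results is not normalized between arrays, per the file headers. The deposited value table was compared with the processed intensity of each array spot by spot, and 0 spots differed, so it gave the same numbers when used as an alternative. The batches were scanned on different days and scanners, per the file headers.

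Log2 values were computed here from the deposited processed intensity, which has no log scale of its own. Control spots and outlier-flagged spots were left out, log2 values were averaged over the remaining ones of the 7 spots of each probe (over all 7 where every spot was outlier-flagged), and the array's 75th percentile was subtracted. Levels in percent are the same values relative to that percentile. The array has 1 probe per gene and 6256 probes. A probe counted as well above background on an array where at least 0.5 of its unflagged spots were, and a gene entered the tests if that held on at least 3 of 14 arrays, which left 6197 genes and removed 59. A total of 5882 genes were well above background on all arrays and 36 on none. Genes carry the systematic names of the array files. Of these 6256 names, 5756 matched the RefSeq gene table of the R64 assembly, whose symbols are used where it has one, and which was used only for names and for which genes lie next to each other. The assembly behind the array design is not given in the sources used here, and no coordinates are printed. Families with near-identical members, such as HXT6 and HXT7, seripauperins and Y prime helicases, are uncertain as single genes.

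Strain differences were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with files read by version 1.17.8 of the package data.table. The fit over both batches had batch and strain as terms and 11 residual degrees of freedom. Each batch was also fitted alone, and the difference between the batches was tested as an interaction. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 and counted again at 1.5-fold. All tests were two-sided. A gene not well above background on any array of a strain was given only a bound on its fold change. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation, and with fry, which tests whether a set's genes move 1 way on balance and compares them with no other genes. Of 41 lists, 40 had at least 3 genes on the array and the list of Ty reading frames had 0. The group assignment, the designs, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

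The genes named are RNH201, RNH202, RNH203, RNH1, TOP1, the nearest gene on each side of RNH201, AGP1, LEU2 and URA3, and then the 12 largest rises and 12 largest falls among genes called over both batches with the same sign in each batch. Added to these are, per list described, up to 4 members with the smallest p and members called at 1.5-fold, and the 5 genes with the smallest interaction p. PDA1, PDB1, PDX1 and LPD1 were named for a test on LAT1, and genes up to 4 places from RNH201 for their position. The values of 1 gene that the rule names are not reported here.

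The fits were tested on simulated data drawn with the real gene means, batch shifts and residual spreads, with 50 genes changed at each fold. Over both batches (6197 genes) 64% of genes changed 1.2-fold, 94% of those changed 1.5-fold, 98% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 5 false calls. In batch 1 the shares were 14%, 80%, 94% and 98% with 5 false calls, in batch 2 40%, 80%, 96% and 98% with 10, and for the interaction 10%, 62%, 90% and 96% with 4. Of 40 simulated lists, all 3 shifted by 0.3 (log2) were called by camera and 0 of the others. The simulated noise was drawn separately for each gene, so genes were not correlated. The 0 false list calls therefore do not cover real genes that move together.

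Alternatives were normexp background correction (offset 50) on mean and local background signals, which at once drops the detrending and surrogate values of the processed intensity and adds an offset, and, changing 1 choice at a time, quantile or median scaling, no filter or well above background on all arrays, no batch term, slide as a fixed or random block, replicate number as a block, array position as a term, array weights, a robust trended variance, the deposited value table, and each array left out in turn. Both wild-type arrays numbered 3 left out and a covariate from trehalose and glycogen genes were added after the data were seen, as were, for the dimmest genes, the single steps between the processed intensity and normexp: the offset alone, the mean signal as it is, the mean signal minus local background with a floor of 1 (0.909% of spots and arrays at it), and normexp without an offset. Taking the brightest probe of a gene could not be run, with 1 probe per gene, and slide as a random block was not run for gene lists. The number of arrays limits the precision of every comparison, and for dim genes the signal over background does.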

Results

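RNase H2 removes ribonucleotides that DNA polymerases place in DNA and cuts the RNA strand of RNA:DNA hybrids, and RNH201 encodes its catalytic subunit. The series asked what the loss of RNase H2 does to the transcriptome of budding yeast, Saccharomyces cerevisiae. Total RNA from mid-log cultures in rich glucose medium was hybridised to 1-colour (Cy3) Agilent arrays with 6256 gene probes. A wild-type MATa strain and the same background carrying a hygromycin cassette in place of RNH201, called rnh201 here, each gave 7 biological replicates, 3 in batch 1 and 4 in batch 2. Each culture started from its own colony. The 75th percentile of the array signal, to which all levels below are relative, lay between 13099 and 18479 in batch 1 and between 6980 and 9128 in batch 2. Between 94.2% and 99.3% of the spots on an array were well above background. The 14 arrays lay on 5 slides. In batch 2 both wild-type arrays of a slide were at positions 1 and 2 and both rnh201 arrays at positions 3 and 4, so position and strain moved together there. The first principal component (56.5% of the variance) separated the batches, and on the second (24.6%) all 7 wild-type arrays lay below 0 and all 7 rnh201 arrays above it.

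RNH201 (YNL072W) was checked first on every array. Its signal was 38.2% ± 1.88 of the 75th percentile in wild type in batch 1 (SD, n = 3) and 48.4% ± 2.24 in batch 2 (SD, n = 4). In rnh201 it was not well above background on any of the 7 arrays, which gives a level at least 304-fold lower (limma adjusted p = 1.3e-18; lower on 7 of 7 arrays). Such counts, here and below, are of rnh201 arrays beyond the wild-type mean of their batch, not beyond every wild-type array. That bound sets the wild-type mean over all 7 arrays against the dimmest signal well above background on each rnh201 array, and it was at least 62.9-fold with the normexp background correction. AGP1 and LEU2, disrupted or deleted in both strains by the labels, were not well above background on any of the 14 arrays. URA3, present in both strains as the reporter gene, had a log2 difference (rnh201 minus wild type) of -0.23 ± 0.04 (SE, n = 7 per strain; adjusted p = 0.000521, lower on 7 of 7 arrays), a call that was lost without a batch term (adjusted p = 0.356).

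The second smallest p of all genes tested, after that of RNH201, belonged to the neighbouring gene. LAT1 (YNL071W) encodes the dihydrolipoamide acetyltransferase of the mitochondrial pyruvate dehydrogenase complex and lies next to RNH201 in the R64 assembly. Its signal was 540% ± 5.37 of the 75th percentile in wild type and 301% ± 5.84 in rnh201 in batch 1 (SD, n = 3 each), and 726% ± 27.7 and 415% ± 17.1 in batch 2 (SD, n = 4 each). The log2 difference was -0.82 ± 0.03 over both batches, 1.77-fold lower (adjusted p = 2.5e-09, lower on 7 of 7 arrays), and it was -0.84 in batch 1 and -0.81 in batch 2. MSK1, the mitochondrial lysyl-tRNA synthetase gene on the other side of RNH201, fell by 0.20 on the log2 scale (adjusted p = 0.0141, 7 of 7 arrays below the wild-type mean of their batch), and this call ended with array position as a term (adjusted p = 0.188), without a batch term (0.0527) and with replicate number as a block (0.0545). The strains overlapped in batch 1, where rnh201 replicate 2 (69.4%) lay above wild-type replicates 1 (66.3%) and 2 (68.2%). Batch 1 alone did not call MSK1 (limma adjusted p = 0.343). Farther out, IMP4 (0.61, adjusted p = 3.5e-05) and FKH2, a forkhead transcription factor gene (0.14, adjusted p = 0.0240), were called higher, while MKS1 (0.02), MLF3 (-0.04), TOM7 (-0.09) and RPL16B (-0.05) were not called. Over both batches the genes of the other RNase H2 subunits rose slightly, RNH202 by 0.12 ± 0.04 and RNH203 by 0.17 ± 0.05 (SE), as did TOP1, topoisomerase I, by 0.16 ± 0.04. Batch 1 alone called none of them (0.083, 0.041 and 0.067, limma adjusted p = 0.481, 0.683 and 0.55). Batch 2 alone, where position and strain moved together, called all of them (0.16, 0.27 and 0.22, limma adjusted p = 0.0333, 0.0056 and 0.00944). RNH1, which encodes the other nuclear RNase H, did not pass (0.02 ± 0.04, adjusted p = 0.734). The RNH202, RNH203 and TOP1 calls were lost under normexp (adjusted p = 0.0685, 0.243 and 0.0917), without a batch term (0.115, 0.146 and 0.627) and with array position as a term (0.125, 0.188 and 0.264). The RNH202 call was also lost with replicate number as a block (0.0773) and without wild-type batch 2 replicate 1 (0.0534).

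**Figure D1:**
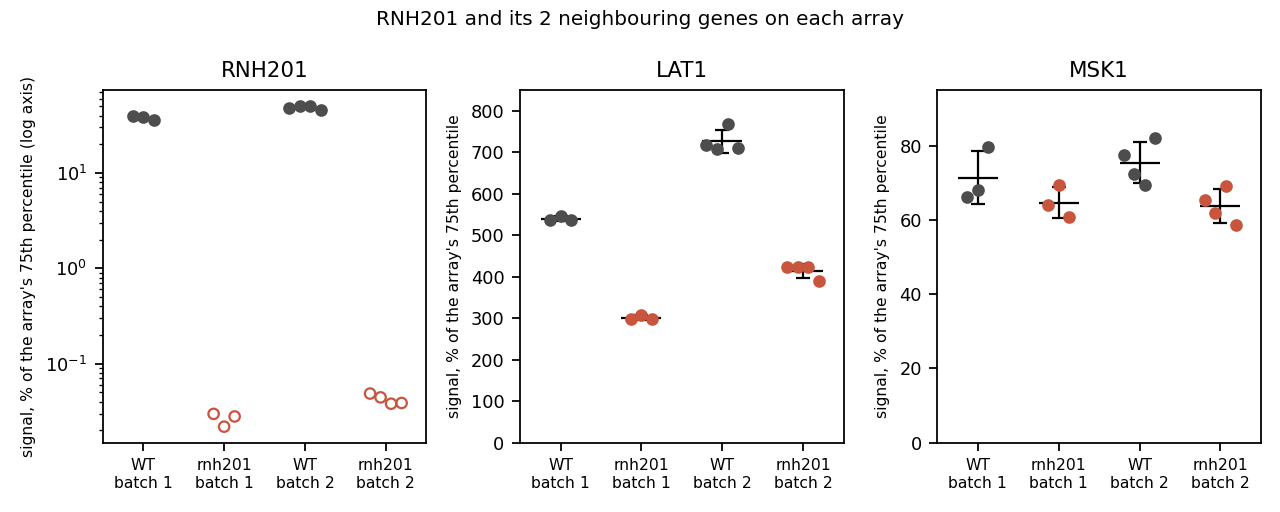
Signal of RNH201 (log axis) and of its neighbours LAT1 and MSK1 (linear axes from 0) on each array, as a percentage of the array's 75th percentile, by strain and batch; filled points were well above background, open points were not, and bars for LAT1 and MSK1 give the mean and SD (n = 3 per strain in batch 1, n = 4 in batch 2). RNH201 lay between 36.1% and 50.2% on the wild-type arrays, and LAT1 was lower on all 7 rnh201 arrays than on the wild-type arrays of its batch.

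Over both batches the expression pattern of rnh201 was one of lower stress, reserve carbohydrate and respiration transcripts and higher ribosome assembly transcripts. GPH1, glycogen phosphorylase, fell by 2.83 ± 0.25 on the log2 scale (SE, n = 7 per strain), 7.10-fold lower, and HXK1, the hexokinase isoform made when glucose is scarce, fell by 2.82 ± 0.22. Glycogen genes GLC3 (branching enzyme, -2.40 ± 0.26), GAC1 (a phosphatase subunit that acts on glycogen synthase, -2.37 ± 0.31) and GSY1 (glycogen synthase, -2.36 ± 0.25) and the trehalose synthase subunit gene TSL1 (-2.21 ± 0.21) were also among the 12 largest falls. The high-affinity glucose transporter genes HXT6 (-2.48 ± 0.29) and HXT7 (-2.44 ± 0.28) are nearly identical in sequence and are uncertain as separate genes. TMA10, YMR206W and EGO4 had -2.81, -2.55 and -2.18. YNL194C completed the set by its fitted value, but it was well above background on 5 of 7 wild-type and 2 of 7 rnh201 arrays, so that value is no measured size. In batch 2, where 4 of 4 wild-type and 0 of 4 rnh201 arrays measured it, its level was at least 6.25-fold lower in rnh201 (limma adjusted p = 9.1e-05 in that batch). With array position as a term YNL194C alone of the 12 lost its call over both batches (adjusted p = 0.211). It also did under normexp (0.0589), and EGO4 did without a batch term (0.107).

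The largest rises were smaller. SIT1, a siderophore transporter, rose by 1.37 ± 0.34 on the log2 scale (SE, n = 7 per strain), and the reductive iron uptake genes FET3 (multicopper oxidase), FRE1 (ferric reductase) and FTR1 (iron permease) rose by 1.22 ± 0.33, 1.17 ± 0.32 and 1.13 ± 0.22. The zinc-responsive gene IZH4 rose by 1.27 ± 0.34, OLE1, the fatty acid desaturase, by 1.06 ± 0.20, and TOD6, a repressor of ribosome biogenesis genes, by 1.11 ± 0.18. YOR338W, PRM7, YNL162W-A, AQR1 and BSC1 made up the rest of the 12 largest rises, at 1.36, 1.10, 1.06, 1.04 and 1.03. SIT1, FET3 and FRE1 were higher on 6 of 7 rnh201 arrays and the other 9 on 7 of 7. Fitted alone, batch 1 called all 12. Batch 2 alone did not call SIT1 (limma adjusted p = 0.107), FET3 (0.197), FRE1 (0.195), PRM7 (0.0953) or BSC1 (0.149). With array position as a term 10 of these 12 calls were lost, as estimates fell and standard errors grew. The 4 iron uptake genes then had 1.21 ± 0.50 (SIT1), 1.00 ± 0.47 (FET3), 0.96 ± 0.47 (FRE1) and 0.96 ± 0.32 (FTR1), OLE1 had 0.90 ± 0.30 and IZH4 0.94 ± 0.51, and the lowest was BSC1, at 0.57 ± 0.52. TOD6 and YNL162W-A kept theirs, but YNL162W-A lost it under normexp (adjusted p = 0.935). The BSC1 call was also lost on leaving out any 1 of 5 arrays (wild-type batch 1 replicate 3, and replicates 2 and 3 of rnh201 in each batch, with a highest adjusted p of 0.0742), under normexp (0.551) and without a batch term (0.0665).

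**Figure D2:**
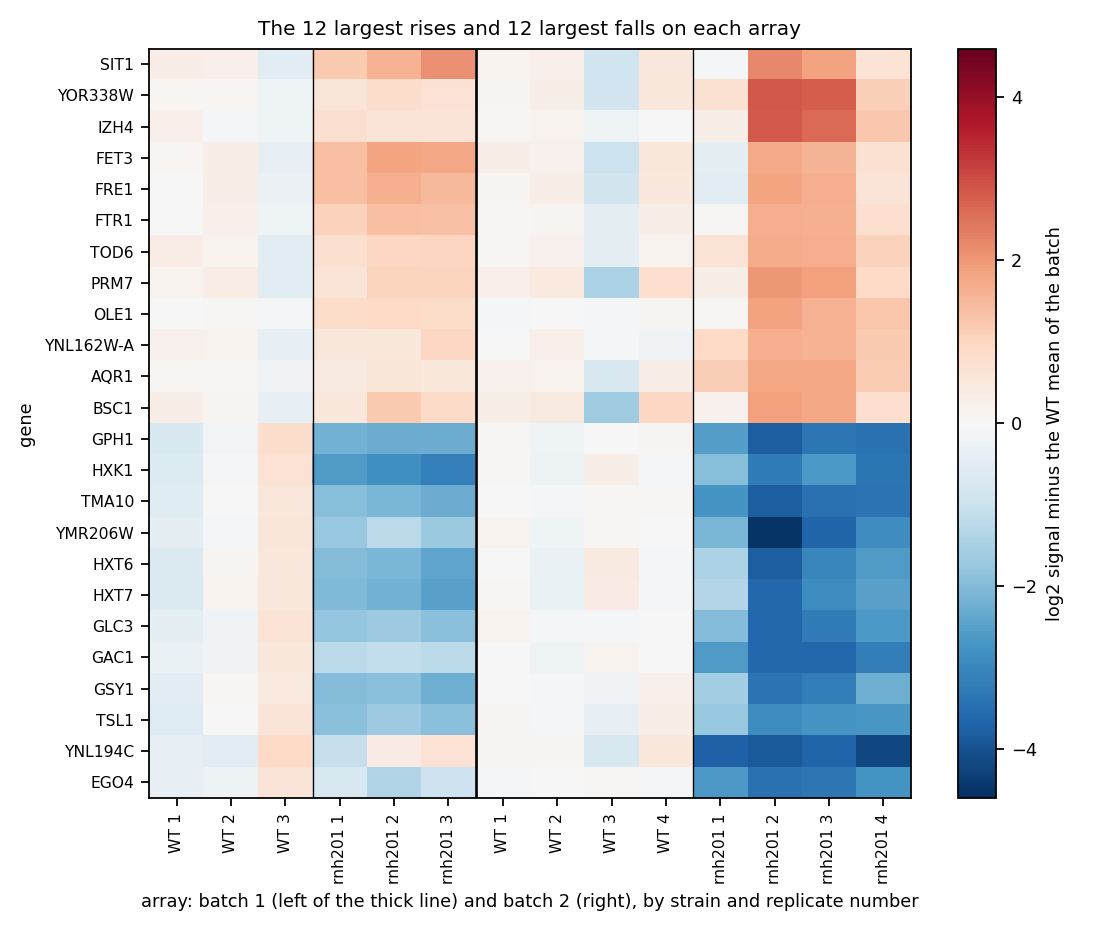
Log2 signal of the 12 genes with the largest rises and the 12 with the largest falls on each of the 14 arrays, minus the wild-type mean of the same batch (colour, full range shown). The falls reach -4.50 on single arrays and the rises 2.87, and rnh201 batch 2 replicate 1 is paler than the other 3 rnh201 arrays of its batch.

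Among all genes, limma with batch as a term called 2623 of 6197 genes at an adjusted p below 0.05, 1413 higher and 1210 lower in rnh201. Most changes were small. Only 377 of the called genes reached 1.5-fold (132 higher, 245 lower) and 103 reached 2-fold (14 higher, 89 lower). Under median scaling 63.0% of the calls were higher, against 53.9% here. Under normexp fewer were higher than lower (786 and 991), and the 1.5-fold calls were 76 higher and 242 lower. Without a batch term, here and below, log2 differences are the same and only their standard errors change. Of 104 named genes that were called, 92 lay beyond the wild-type mean of the batch, in the stated direction, on all 7 rnh201 arrays and the others on at least 5. Without the wild-type arrays numbered 3, which stood apart from their groups in both batches, 2410 genes were called and 333 at 1.5-fold (chosen after the data were seen). The count was 998 without the batch term and 1043 with array position as a term, which left 195 genes at 1.5-fold. With the mean level of the trehalose and glycogen genes on each array as a covariate, a setting chosen after the data were seen, only 2 genes, RNH201 and LAT1, were called (466 at an unadjusted p under 0.05), 48 of 98 named genes called before had the other sign, and the median standard error went from 0.0606 to 0.158.

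The genes were then grouped by lists of known function. Where a list below is given in 1 direction only, limma called no member the other way. There were 14 such cases over all lists, and at an unadjusted p under 0.05 they held 2 members in the direction not called. Genes that yeast induces under many stresses fell almost as a block. Of 40 measured members of the environmental stress response list, 39 fell, with a median log2 difference of -1.13 (-0.77 in batch 1, -1.24 in batch 2). Examples besides HXK1 and GPH1 were GAD1 (glutamate decarboxylase, -1.54 ± 0.13), GLK1 (glucokinase, -1.33 ± 0.11), CTT1 (catalase, -1.33 ± 0.20) and HSP104 (protein disaggregase, -1.12 ± 0.11), with SE over 7 arrays per strain. In trehalose and glycogen metabolism, which shares 9 genes with that list, 15 of 17 fell and 1 rose (median -0.78), among them GSY2 (glycogen synthase, -1.72 ± 0.16) and UGP1 (UDP-glucose pyrophosphorylase, -0.74 ± 0.08). The competitive set test camera, at a preset inter-gene correlation of 0.01, gave adjusted p = 5.2e-23 for the stress list and 2.8e-10 for the reserve carbohydrate list. With an estimated correlation neither passed, at adjusted p = 0.448 and adjusted p = 0.522. Among heat shock factor targets 10 of 23 fell (median -0.18, adjusted p = 0.0108, and adjusted p = 0.741 with an estimated correlation), including HSP104, the small chaperone HSP42 (-1.57 ± 0.20), the mitochondrial disaggregase HSP78 (-1.33 ± 0.16) and the J-protein MDJ1 (-0.45 ± 0.06). HSP104 and HSP42 are among 4 genes that this list shares with the stress list. Of 21 oxidative stress targets 7 fell and 1 rose (median -0.21, adjusted p = 0.0278, and adjusted p = 0.802 with an estimated correlation), including GSH1 of glutathione synthesis (-0.45 ± 0.10). Without a batch term UGP1 (adjusted p = 0.0671), MDJ1 (0.322) and GSH1 (0.0571) were not called, nor was GSH1 with array position as a term (0.107).

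Respiration genes moved the same way. In oxidative phosphorylation 37 of 39 genes fell (median -0.37, camera adjusted p = 1.3e-13, and adjusted p = 0.741 with an estimated correlation). The alternative subunits CYC7 (cytochrome c isoform 2, -1.91 ± 0.23) and COX5B (cytochrome c oxidase subunit Vb, -1.33 ± 0.15) fell most clearly, together with the succinate dehydrogenase genes SDH1 (-0.91 ± 0.12) and SDH4 (-0.65 ± 0.08). In the tricarboxylic acid and glyoxylate cycles, which share 4 genes with that list, 15 of 28 fell and 3 rose (median -0.17, adjusted p = 0.00133, and adjusted p = 0.741 with an estimated correlation), with CIT1 (citrate synthase) at -0.87 ± 0.10 and MDH1 (malate dehydrogenase) at -0.80 ± 0.10. Glucose-repressed genes were mixed: 13 of 30 fell and 4 rose (median -0.10, adjusted p = 0.0178, and adjusted p = 0.802 with an estimated correlation), the maltase gene MAL12 falling by 0.70 ± 0.07 and SFC1, a mitochondrial succinate-fumarate carrier, rising by 0.86 ± 0.18 except under normexp (adjusted p = 0.831). Hexose transporters divided, 6 of 19 higher and 6 lower. HXT4 (-1.88 ± 0.20), HXT6, HXT7 and the glucose sensor SNF3 (-0.49 ± 0.07, adjusted p = 0.0539 without a batch term) fell. The low-affinity transporter HXT1 had 0.75 ± 0.26, a call lost on leaving out any 1 of 6 arrays (replicate 3 of wild type, or replicates 2 and 3 of rnh201, in each batch, with a highest adjusted p of 0.0712), with array position as a term (0.470), without a batch term (0.112) and under normexp (0.0542). The list's median was 0.14 and its mean -0.25, and camera did not call it (adjusted p = 0.672). In glycolysis and fermentation 6 of 21 fell and 1 rose (median -0.05, adjusted p = 0.0281, and adjusted p = 0.802 with an estimated correlation), the minor isoenzyme genes TDH1 (-0.83 ± 0.11), ENO1 (-0.54 ± 0.07) and ADH5 (-1.05 ± 0.18) among them.

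**Figure D3:**
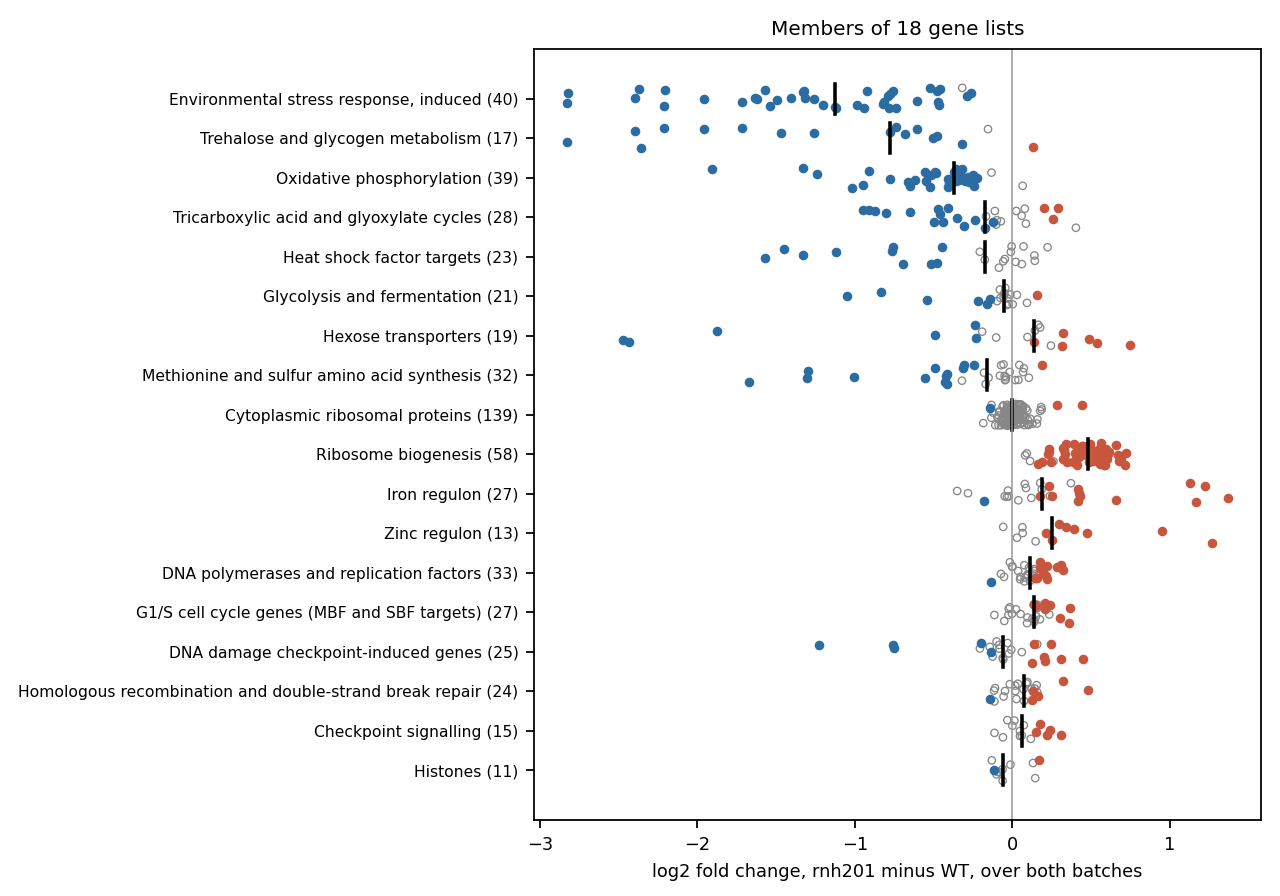
Log2 difference (rnh201 minus wild type, over both batches) of each measured member of 18 gene lists, with the number of members in brackets; filled red points were called higher, filled blue points called lower, open points not called, and black ticks are list medians, with height within a line random. Of the stress-induced list 39 of 40 members lie among the calls below 0, and 54 of 58 ribosome biogenesis genes among those above it.

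Ribosome assembly went the other way. Of 58 ribosome biogenesis genes 54 rose (median 0.48; 0.57 in batch 1 and 0.41 in batch 2; camera adjusted p = 1.1e-18, and adjusted p = 0.522 with an estimated correlation). The small-subunit processome genes IMP4 (0.61 ± 0.06), SOF1 (0.59 ± 0.07) and UTP5 (0.71 ± 0.10), the helicase gene DBP8 (0.72 ± 0.12) and RPA43, a subunit of RNA polymerase I (0.49 ± 0.06, adjusted p = 0.106 without a batch term), were examples. Cytoplasmic ribosomal proteins themselves showed no shift, with 2 of 139 list members higher and 1 lower and a median of -0.00, whose sign turned under normexp, quantile and median scaling. The members called higher were RPP1 (0.44), a subunit of RNase P that the name pattern took in, and RPS9A (0.29, adjusted p = 0.101 with array position as a term).

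In the iron regulon 12 of 27 genes rose and 1 fell (median 0.19, adjusted p = 0.0335, and adjusted p = 0.827 with an estimated correlation). That call depended on single arrays and settings: it was lost without both wild-type arrays numbered 3 (adjusted p = 0.416, chosen after the data were seen), without wild-type batch 1 replicate 3 (0.093) or batch 2 replicate 3 (0.180), without rnh201 batch 1 replicate 2 (0.053) or batch 2 replicates 2 (0.0577) or 3 (0.0601), with array position as a term (0.296), with array weights (0.187), under median scaling (0.0795) and quantile normalization (0.0537) and by fry (0.0775), and it turned to -0.09 with the trehalose and glycogen covariate (adjusted p = 0.0246). In the zinc regulon 8 of 13 rose (median 0.25, adjusted p = 0.0109, and adjusted p = 0.448 with an estimated correlation), including the regulator ZAP1 (0.34 ± 0.06), the membrane protein gene IZH1 (0.95 ± 0.17) and the vacuolar zinc transporter ZRC1 (0.29 ± 0.05). The ZAP1 call was lost under normexp (adjusted p = 0.806) and without a batch term (0.687), and those of IZH1 (0.0583) and ZRC1 (0.0563) with array position as a term.

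Amino acid genes changed unevenly. Of 32 genes of methionine and sulfur amino acid synthesis 13 fell and 1 rose (median -0.16, adjusted p = 0.00109, and adjusted p = 0.741 with an estimated correlation). STR3 (cystathionine beta-lyase, -1.67 ± 0.19), the transcription factor MET28 (-1.31 ± 0.17) and MET2 (homoserine acetyltransferase, -1.01 ± 0.16) fell most among its 4 most significant members. The Gcn4-regulated synthesis list was not called, with 7 of 46 higher and 8 lower, but HIS4 of histidine synthesis fell by 1.57 ± 0.23. Seripauperin genes, a subtelomeric family with near-identical members, had 7 of 24 lower (median -0.13, adjusted p = 0.0178, and adjusted p = 0.827 with an estimated correlation).

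Genome maintenance genes moved little. In the list of DNA polymerases and replication factors 12 of 33 rose and 1 fell (median 0.11, adjusted p = 0.00505, and adjusted p = 0.741 with an estimated correlation), including DPB4, a subunit of DNA polymerase epsilon (0.31 ± 0.05), POL3, the catalytic subunit of polymerase delta (0.22 ± 0.04), and SLD3, needed for origin firing (0.32 ± 0.06). Among G1/S genes, 7 of which are on that list too, 8 of 27 rose (median 0.14; -0.0095 in batch 1 and 0.23 in batch 2; adjusted p = 0.0278, and adjusted p = 0.827 with an estimated correlation). CDC6 (0.36 ± 0.06) and RNR1, the large subunit of ribonucleotide reductase (0.21 ± 0.05), were among them. Genes induced by the DNA damage checkpoint did not move together: 7 of 25 rose and 5 fell, with a median of -0.06 (adjusted p = 0.513). SML1, the ribonucleotide reductase inhibitor, rose by 0.31 ± 0.05, while UBI4 (polyubiquitin, -0.75 ± 0.08), PHR1 (photolyase, -0.76 ± 0.11) and the transcription factor TOS8 (-1.23 ± 0.22) fell. Homologous recombination had 5 of 24 higher and 1 lower (adjusted p = 0.311), with TOP3 at 0.48 ± 0.09 and SLX4 at -0.14 ± 0.04. Checkpoint signalling had 5 of 15 higher (adjusted p = 0.243), with RAD9 (0.31 ± 0.07) and DPB11 (0.24 ± 0.05), and post-replication repair 4 of 13 higher (adjusted p = 0.302), with the translesion polymerase REV1 at 0.33 ± 0.05. In the list of RNase H2 subunits and hybrid removal 7 of 17 rose and 3 fell, the falls being RNH201, TDP1 (tyrosyl-DNA phosphodiesterase, -0.28 ± 0.05) and APN2 (abasic endonuclease, -0.22 ± 0.04), and its median of 0.07 was unchanged with RNH201 at its bound. TOP3 (adjusted p = 0.714), SLD3 (0.0911) and CDC6 (0.139) were not called under normexp. With array position as a term POL3 (0.0519), RNR1 (0.0750), RAD9 (0.155), TOS8 (0.0624), APN2 (0.0586), SLX4 (0.0718) and TOP3 (0.0563) lost their calls, and without a batch term CDC6 (0.292), DPB11 (0.305), REV1 (0.108), SLX4 (0.526) and APN2 (0.148) did. Of 11 histone genes HTB1 (-0.12) and HTB2 (0.17) were called by a margin that ended on leaving out any 1 of 8 and of 10 arrays (highest adjusted p 0.0759 and 0.0873).

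The remaining lists were not called by camera. Ergosterol synthesis had 11 of 25 genes higher and 4 lower, meiosis and sporulation 10 of 31 and 2, telomere factors 7 of 18 and 2, pyrimidine and deoxynucleotide synthesis 8 of 20 and 3, nitrogen catabolite-repressed genes 8 of 27 and 2, purine synthesis 8 of 26 and 5, excision and mismatch repair 5 of 19 and 1, and G2/M genes 5 of 26 and 1. More genes were lower than higher in the cell wall list (10 of 32 against 4), mitochondrial ribosomal proteins (8 of 67 against 0), Pdr1 targets (4 of 17 against 1), pheromone response genes (4 of 26 against 2), the phosphate regulon (2 of 20 against 1) and the proteasome (2 of 33 against 0). Of 6 alpha mating genes 1 was higher, and none of the 8 Y prime helicase genes, a near-identical family, was called either way by limma, with 0 at an unadjusted p under 0.05. Adjusted over the list alone, the called lists gave the counts stated above, except 55 rises in ribosome biogenesis, 16 falls in trehalose and glycogen metabolism and 5 rises among glucose-repressed genes. With the lists not called included, 20 lists gave other counts. The largest change was in mitochondrial ribosomal proteins, with 1 fall in place of 8, and the proteasome had 0 in place of 2. In all 5 lists rose and 10 fell by camera, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05), where the lowest adjusted p was 0.448, and fry called 18. The smallest p by fry was that of the RNase H2 list (lower, adjusted p = 2.7e-07). That list holds the deleted RNH201 and its median was 0.07, so the deletion itself set this call.

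Of the 15 list calls, 6 were lost on leaving out a single array: the iron regulon as given above, seripauperin genes without wild-type batch 1 replicate 1 (adjusted p = 0.0534), glucose-repressed genes without wild-type batch 1 replicate 3 (0.0512), oxidative stress targets without rnh201 batch 1 replicate 3 (0.0506), glycolysis without that array (0.055) or wild-type batch 2 replicate 3 (0.0784), and G1/S genes without wild-type batch 2 replicates 2 (0.0511) or 4 (0.0525) or rnh201 batch 2 replicate 1 (0.124). Without both wild-type arrays numbered 3, the calls of the oxidative stress (adjusted p = 0.0609), glycolysis (0.105) and glucose-repressed lists (0.0698) ended too. With array position as a term those of glycolysis (0.0806), G1/S (0.127) and glucose-repressed genes (0.0505) were lost. The glycolysis call was also lost under normexp (0.0879), quantile normalization (0.0506) and median scaling (0.0546) and with array weights, the oxidative stress call under normexp (0.0711) and with array weights (0.0513), the G1/S call without a batch term (0.0607) and by fry (0.0918), and the seripauperin call by fry (0.166). The trehalose and glycogen covariate ended 11 list calls, at adjusted p from 0.166 to 0.890. With it the median of ribosome biogenesis was 0.14, and those of 6 lists had the other sign: oxidative phosphorylation (0.024), methionine synthesis (0.023), oxidative stress (0.13), glucose-repressed genes (0.049), glycolysis (0.017) and seripauperin genes (0.018).

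The medians of the called lists had the same sign in both batches except that of G1/S genes. In batch 1 and batch 2 they were -0.62 and -0.90 for trehalose and glycogen, -0.42 and -0.38 for oxidative phosphorylation, and -0.31 and -0.091 for the tricarboxylic acid cycle. Heat shock targets had -0.26 and -0.041, oxidative stress targets -0.24 and -0.14, glucose-repressed genes -0.20 and -0.093, and glycolysis -0.073 and -0.045. Methionine synthesis had -0.17 and -0.16, seripauperin genes -0.090 and -0.17, the zinc list 0.37 and 0.18, the iron list 0.12 and 0.22, and polymerases and replication factors 0.051 and 0.14. Whether a list's shift differed between the batches was not tested.

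Each batch was then fitted alone to see whether the strain difference recurred. In both, stress and glycogen genes fell and ribosome biogenesis genes rose: HXK1 had -2.86 ± 0.30 in batch 1 and -2.79 ± 0.28 in batch 2, and GPH1 -2.25 ± 0.33 and -3.26 ± 0.23. Batch 1 (3 arrays per strain) called 1067 genes, 481 higher and 586 lower, and batch 2 (4 per strain) called 2392, 1389 higher and 1003 lower. Of the genes called, 725 were shared, and 716 of these had the same sign (340 higher, 376 lower), against 203 that independent lists of these sizes would share in the same direction. The batches have no control array in common. Across genes, which are not independent replicates, the log2 differences of the batches had Pearson r = 0.696 and Spearman rho = 0.604. RNH201, whose deletion fixed its fall, was among these genes at fitted values of -10.5 and -10.2, which raises Pearson r. The correlation without RNH201 was not computed. Of all genes tested, 70.6% had the same sign in both batches.

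**Figure D4:**
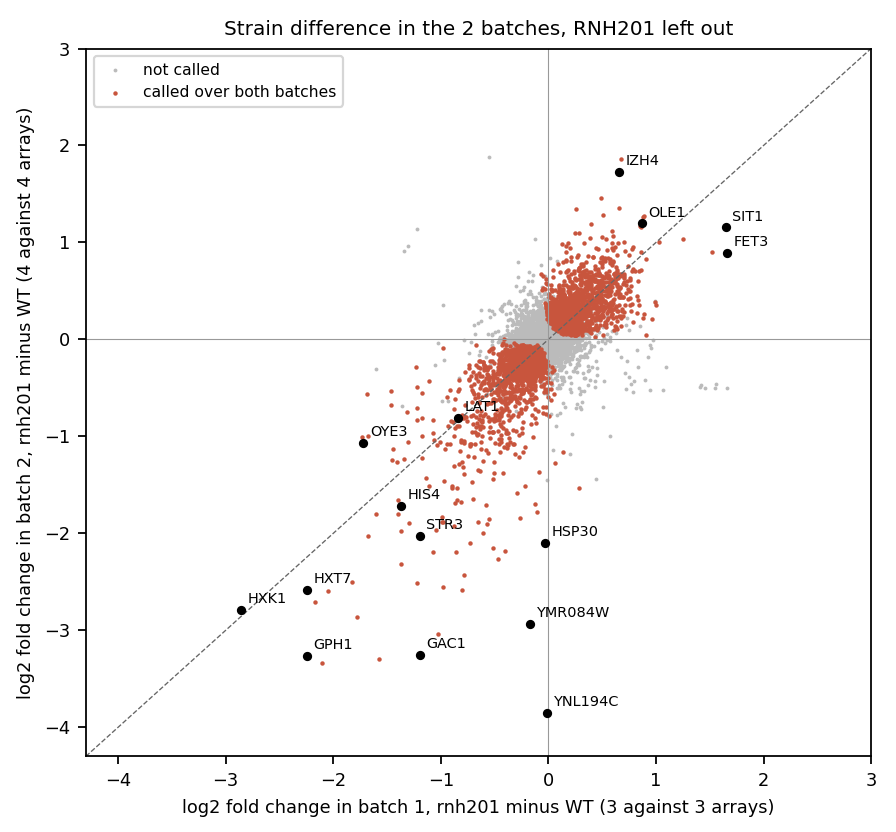
Log2 difference (rnh201 minus wild type) of each gene in batch 1 (horizontal axis, 3 arrays per strain) against batch 2 (vertical axis, 4 arrays per strain), RNH201 left out; red points were called over both batches, grey points were not, black points carry gene names, and the dashed line marks equal differences. Stress and glycogen genes such as HXK1 and GPH1 lie low in both batches, while HSP30 had -0.03 in batch 1 and -2.10 in batch 2, and the point of YNL194C is a fitted value of a gene that no rnh201 array of batch 2 measured above background.

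The batch 1 count depended on single arrays, with 170 genes without rnh201 replicate 3, 575 without rnh201 replicate 2, 711 without rnh201 replicate 1 and 458 without wild-type replicate 2. It was 2 with slide as a fixed block, where rnh201 replicate 1 was alone on its slide and so could not inform the strain difference. That fit left few degrees of freedom. Under median scaling 56.0% of the batch 1 calls were higher against 45.1% here, while batch 2 gave 988 calls under normexp.

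The strain difference itself varied between the batches for a small set of genes, tested as the interaction of strain and batch. HSP30, a plasma membrane heat shock protein gene, differed little between strains in batch 1 (-0.03 ± 0.10) and fell by 2.10 ± 0.10 on the log2 scale in batch 2, an interaction (batch 2 minus batch 1) of -2.07 ± 0.15 (adjusted p = 2.2e-05). The cell wall protein gene PIR3 (-1.57 ± 0.16, adjusted p = 0.000806), YMR084W (-2.76 ± 0.36, adjusted p = 0.00669), RGI1, linked to respiratory growth (-1.65 ± 0.22, adjusted p = 0.00855), and YGR126W (-0.86 ± 0.12, adjusted p = 0.00863) followed. The wild type itself shifted between batches: HSP30 stood at 48.5% of the 75th percentile in batch 1 and 840% in batch 2, against 47.5% and 196% in rnh201. Wild-type levels were also higher in batch 2 than in batch 1 for PIR3 (25.8% against 4.28%), YMR084W (2.99% against 0.769%), RGI1 (695% against 169%) and YGR126W (1.44% against 0.888%). The interaction was also called for the stress gene YNL194C (adjusted p = 0.00988), but only 1 of 3 wild-type and 2 of 3 rnh201 arrays of batch 1 and no rnh201 array of batch 2 measured it above background, so its size is not given. In all 173 genes were called, 96 with a more positive difference in batch 2 and 77 with a more negative one (55.5% more positive, against 41.0% under quantile normalization and 42.9% under median scaling). Under normexp 3 genes were called, HSP30, PIR3 and RGI1, but not YMR084W (adjusted p = 0.131) or YGR126W (0.495). Leaving out wild-type batch 2 replicate 3 gave 382 and rnh201 batch 2 replicate 1 gave 278. Without wild-type batch 1 replicate 3 the count was 140, with 46 more positive and 94 more negative. Lower counts came without wild-type replicates 1 (52) and 2 (37) or rnh201 replicates 2 (67) and 3 (48) of batch 1, and without wild-type replicates 1 (35), 2 (47) and 4 (51) or rnh201 replicates 2 (48) and 3 (55) of batch 2.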

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

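The rank used for a local effect at the RNH201 locus, the test of the negative controls, the covariate from trehalose and glycogen genes, the values by slide, the single steps between the processed signal and normexp, the splits for list medians and the removal of both wild-type arrays numbered 3 were chosen only after results were seen.

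The lower stress, reserve carbohydrate and respiration genes with higher ribosome biogenesis genes form the first pattern a biologist would want to follow up. With array position as a term, the stress-induced list kept a median log2 difference of -0.95 (jackknife SE 0.15) and ribosome biogenesis 0.43. That fit separates position from strain only through batch 1, since the 2 moved together in batch 2. It speaks against position effects alike in both batches but cannot exclude one in batch 2 alone. The 2 wild-type arrays numbered 3 do not account for the pattern, since without them the medians were -1.12 (jackknife SE 0.146) and 0.43. The stress medians on the 4 slides that held both strains were -0.80, -0.79, -1.38 and -1.15. Cultures collected at different points of growth may be the cause and cannot be told apart from an effect of RNase H2 loss: the strain difference of one batch and the main axis of differences between replicate cultures of the other correlated across genes at 0.245 and 0.480, between the values set for either outcome, and strain held 87.6% of the within-batch variance of the trehalose and glycogen score. The score also differed between batches within a strain. On wild-type arrays it lay between -0.27 and 0.36 in batch 1 and between 0.95 and 1.14 in batch 2. On rnh201 arrays it lay between -0.96 and -0.84 and between -0.62 and 0.07. The strain difference of the score was -1.20. Whether culture state or the different scanners shifted it between batches was not tested. No cell density per culture was used here, and an effect of the missing enzyme stays open as well.

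LAT1 is the second pattern, with a signal far from the rest of its group on wild-type batch 2 replicate 3 (highest, 767% of the 75th percentile, gap over range 0.838) and on rnh201 batch 2 replicate 4 (lowest, 389% against 423%, 0.982). Its fall stayed at -0.85 ± 0.10 (SE) with the trehalose and glycogen score as a covariate, which speaks against a shared growth shift. Strain held 87.6% of the within-batch variance of that score, so the covariate cannot exclude such a shift. A fall of the whole pyruvate dehydrogenase complex does not account for it, since PDA1 (-0.02), PDB1 (0.08), PDX1 (-0.18) and LPD1 (-0.12) had a median of -0.074. A local effect of the cassette or of the deleted segment on LAT1 transcription stays open as a hypothesis without a test, since the rank of LAT1 by p, 2 among all genes tested, is what drew attention to it and does not bear on whether the effect is local. The arrays hold no strain with RNase H2 lost in another way that could separate it from an effect of the missing protein.

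Genes near background form the third pattern: of the 620 genes with the lowest mean signal, 151 were called higher and 55 lower (median 0.06), and they held 32 of the 132 rises of at least 1.5-fold. Under normexp their median was -0.42 (0.016 in batch 1, -0.74 in batch 2), with 0 higher and 8 lower, but that setting also starts from signals without detrending or surrogate values and adds an offset. Taken singly, the offset gave a median of -0.0027 (80 higher, 55 lower), the mean signal without background removal -0.018 (71 and 59) and plain subtraction of the local background from it 0.020 (more called higher than the 68 called lower), while normexp without an offset gave -0.53 (0 and 10), so the large fall came with the normexp model and not with plain subtraction on the same signals. An additive background effect may underlie this pattern and cannot be told apart from a difference in transcripts, since the sign of so small a median differs between these settings. Negative control spots, a test that replaced one on the genes' level over background because choosing dim genes fixed its outcome, did not settle it, with a difference (rnh201 minus wild type, relative to the 75th percentile) of 0.07 in batch 1 and -0.50 in batch 2 on the log2 scale.

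Other splits of the same arrays were fitted to see whether chance could give as much. For the calls over both batches, 1 of 100 splits (the real one) gave as many as 2623, the highest other, which kept 12 of 14 arrays on their own side, giving 1664. The same held at 1.5-fold (377 against 243) and in batch 2 (2392 against 0, 1 of 35), so chance can be excluded for these. For the interaction, the fitted batch effect was removed and batch labels were permuted within strain. The real labels gave 173 calls and the highest other 15 (1 of 100 as large). That comparison is approximate, since the removed effect was estimated with the real labels. Batch 1 has 10 splits, too few for a share under 0.05 (1067 against 19, 1 split as large). For the number of gene lists called, 43 of 100 splits gave 15 or more and the highest other gave 24, so chance cannot be excluded for that number. For the medians of the stress-induced, ribosome biogenesis, oxidative phosphorylation, trehalose and glycogen, zinc, polymerase, ergosterol and pyrimidine lists, the real split alone of the 100 was as large. Of the other lists called by camera, methionine synthesis and oxidative stress had 2 splits as large, the tricarboxylic acid cycle 3, and G1/S and seripauperin genes 4. Heat shock targets had 5, the iron list 13, glucose-repressed genes 14 and glycolysis 23, so chance cannot be excluded for the medians of these.

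Of 211 tests of whether 1 array of a batch 2 group of 4 lies far from the other 3 (Dixon's ratio of gap to range, at its 95% critical value), 14 exceeded it, where chance alone, 1 in 20, gives about 10.6. Besides LAT1 these were, in wild type, OLE1 (0.957, replicate 4 highest), AQR1 (0.854, replicate 3 lowest), RGI1 (0.948, replicate 4 highest), COX5B (0.833, replicate 3 highest), TOP2 (0.846, replicate 4 highest), PHR1 (0.832, replicate 2 lowest), RAD9 (0.836, replicate 3 lowest) and PAU7 (0.836, replicate 3 lowest). In rnh201 they were GLK1 (0.845), MDH1 (0.889), HSP78 (0.907) and TDH1 (0.979), each highest on replicate 1. By array, 5 of the 14 came from wild-type replicate 3 and 4 from rnh201 replicate 1.

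The strain difference differed between batches by the interaction test for 12 named genes. Given as batch 2 minus batch 1 on the log2 scale, it was -2.76 for YMR084W, -2.07 for HSP30, -2.06 for GAC1, -2.01 for EGO4, -1.65 for RGI1, -1.57 for PIR3, -1.32 for CTT1, -0.86 for YGR126W and -0.74 for PHR1. The fitted value of YNL194C was -3.84, which is no measured size, since no rnh201 array of batch 2 and only 3 of 6 arrays of batch 1 measured that gene above background. The difference was 0.37 for THP2 and 0.59 for RMI1.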

How the results depend on the processing

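The trehalose and glycogen covariate and the removal of both wild-type arrays numbered 3 are settings chosen only after the data were seen. Over both batches 2623 calls became 998 without a batch term, 1043 with array position as a term (195 in place of 377 at 1.5-fold) and 2 with the covariate (2 at 1.5-fold). With the covariate 8 gene lists were called, all lower: the stress and heat shock lists as before, the iron list reversed, and 5 not called before (histones, mitochondrial ribosomal proteins, cell wall, proteasome and Pdr1 targets). An estimated correlation left 0 of 15 lists. Normexp gave 988 calls in batch 2, 3 for the interaction and r = 0.588 between batches (RNH201 included), and slide as a block left 2 calls in batch 1, which has 3 slides for its arrays. Of these, slide 3 held only rnh201 replicate 1, so that array could not inform the strain difference and few degrees of freedom were left. The cause of the other changes was not tested, with 2 exceptions. Without a batch term the log2 differences are the same, since each batch holds as many arrays of each strain, and only the errors change (URA3 -0.23 with SE 0.0403 and 0.144). The covariate carries 87.6% of its within-batch variance as strain and the median standard error grew 2.77 times with it.

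With the covariate, of 98 named genes called without it, RNH201 and LAT1 were still called, 48 kept their direction without a call and 48 changed sign, none of these called. Log2 differences above 0 in place of falls were YNL194C 1.43, YMR084W 1.06, YMR206W 0.78, TOS8 0.64, ADH5 0.45, OYE3 0.43, HSP30 0.41, CTT1 0.32, GAC1 0.21, HSP42 0.20, GSH1 0.20, MET28 0.15, HIS4 0.15, EGO4 0.14, RGI1 0.13, MSK1 0.10, PHR1 0.098, HSP78 0.092, SNF3 0.039, TDH1 0.034, STR2 0.032 and MDH1 0.014. Those below 0 in place of rises were IZH4 -1.50, YOR338W -0.94, HXT1 -0.59, IZH1 -0.52, PRM7 -0.45, OLE1 -0.39, YNL162W-A -0.36, TOD6 -0.32, BSC1 -0.29, DBP8 -0.29, RMI1 -0.22, RPS9A -0.17, UTP5 -0.16, SIT1 -0.15, HTB2 -0.12, PCL2 -0.088, RPP1 -0.080, AQR1 -0.053, TOP1 -0.046, SML1 -0.043, POL32 -0.036, RAD9 -0.034, SLD3 -0.028, FRE1 -0.021, THP2 -0.0071 and DPB4 -0.00042. The iron list turned from 0.19 to -0.094 and was called lower.

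With 1 array left out the counts ran from 2288 to 2730 over both batches, 318 to 460 at 1.5-fold, 13 to 16 lists, 170 to 884 in batch 1, 1852 to 2715 in batch 2 and 35 to 382 for the interaction, and r (RNH201 included) from 0.619 to 0.720. In the other settings run, total counts stayed within 1.5 times, with 1777 calls (44.2% higher) under normexp, where higher calls went from 1413 to 786 and rises of 1.5-fold from 132 to 76, 2757 under quantile and 2805 under median scaling, 2410 without the arrays numbered 3, and 2683 and 2723 with slide as a fixed or random block. By direction, quantile normalization raised the more negative interactions from 77 to 118, and fry the higher lists from 5 to 8. The RNH201 bound was 62.9-fold under normexp and 274-fold to 327-fold with 1 array left out. Apart from the covariate, named genes kept direction and side of the threshold in 2816 of 2965 values, 146 lost the call, 1 gained it (YGR126W with array weights) and 2 uncalled ones changed sign, and 49 genes were called in every such setting. Array position ended 41 of these calls, no batch term 31 and normexp 19.

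Replicate numbers do not pair the samples: deviations of same-numbered cultures correlated at -0.263 to 0.312, above 0.1 in 3 of 7 pairs, and not every array correlated best with its own number. With the replicate block 2192 genes were called over both batches (367 at 1.5-fold, 15 lists), 839 in batch 1 and 1990 in batch 2. The brightest probe alternative and a random slide block for lists were not run. Signal over background limits the dimmest genes, and the number of arrays limits the rest.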

Other observations

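The process terms of the array's own annotation, the values by expression level and the test on highly expressed genes were chosen only after results were seen.

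Outside the lists above, RNA processing terms stood out. Of 67 annotated process terms with at least 10 measured genes, camera called 19. Genes of messenger RNA export from the nucleus rose, 18 of 31 (median 0.16, adjusted p = 7.9e-05, and adjusted p = 0.359 with an estimated correlation), and of 57 messenger RNA splicing genes 24 rose and 2 fell (median 0.11, adjusted p = 0.00159, and adjusted p = 0.359 with an estimated correlation). Neither term holds a gene of the lists described above. The 35S transcript processing term (19 of 20 higher, median 0.35) and RNA polymerase I transcription (12 of 16 higher, median 0.41) moved in the same direction as the ribosome biogenesis list, with adjusted p = 0.359 each with an estimated correlation. Vacuole and secretion terms fell: protein-vacuolar targeting had 9 of 21 lower and 1 higher (median -0.13), vesicle-mediated transport 8 of 16 lower (median -0.11) and vacuolar acidification, the proton pump genes, 5 of 10 lower (median -0.11), with adjusted p = 0.0157, 0.0264 and 0.0407, and adjusted p = 0.383, 0.359 and 0.606 with an estimated correlation.

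Hybrids of RNA and DNA form at highly transcribed genes, and a hypothesis was that transcripts of the most highly expressed genes fall without RNase H2. The tenth of genes with the highest signal had a median log2 difference of -0.011, with 77 of 620 called higher and 79 lower. A median near 0 over genes that go both ways, on arrays scaled at their own 75th percentile, decides nothing, and the hypothesis stays open.

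A further hypothesis was that genes next to chromosome ends change together, since RNase H activity acts on telomeric RNA. The first 10 annotated genes from each end of 16 chromosomes (300 of 320 tested) had a median of -0.024, outside the -0.01 to 0.04 that 10000 random sets matched on mean signal gave, with 47 called higher and 63 lower. It was -0.077 in batch 1 and only -0.013 in batch 2, the larger batch. The shift is very small, it was -0.15 under normexp, and these genes are dim, so it may come from the processing of dim signals as well as from location.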
